A study of Homo sapiens with 8 samples.

How the data were processed

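Strand-specific paired-end libraries of total RNA, read at 100 bp on the DNBSEQ platform per the labels, were made from DND-41 and MOLT-4 cells after 8 h with 100 nM ACBI-1 or DMSO. There were 8 libraries in 4 groups of 2. Groups were taken from the labels, and every count column was mapped to a library. The reads were aligned and counted with STAR 2.5.2a and featureCounts on the hg19 build, all named in the submitters' processing notes without their order, and the deposited counts are unnormalized whole numbers per gene. The annotation, the strand setting and any read filter are not given in the sources used here. Per the file headers, the authors' deposited tables also hold log2 fold changes with standard errors, and the submitters' processing notes name DESeq2 1.12.4. Per the file headers, these tables also hold p-values and adjusted p-values by the authors, and their names give DESeq2 as the tool. The score columns deposited by the authors are a mean of normalized counts and a test statistic, per the file headers. The direction of the authors' contrast is not stated in the headers, while the names of both tables read DMSO vs ACBI.

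The 2 count tables held the same 63677 gene identifiers, all with a symbol, and were joined by identifier. Library totals ran from 19860759 to 20239888 counts, so 3 counts equal about 0.15 CPM. Replicates had Pearson's r of log2 CPM from 0.9957 to 0.9977, and no 2 libraries were identical. Levels are CPM over effective library sizes. A reference annotation of another genome build was used only by gene identifier, for gene type, length and GC content.

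Each line was tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr at its minimum count of 10, scaled by TMM, and tested by the quasi-likelihood F test with treatment as the only term. Adjusted p-values follow Benjamini and Hochberg, with a threshold of 0.05. Each SE is the absolute log2 fold change divided by the square root of the F statistic. It therefore also draws on the spread of other genes. The difference between lines was the interaction of line and treatment over all 8 libraries, as MOLT-4 minus DND-41. The overlap of calls was tested by Fisher's exact test, one-sided, in each direction.

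The 25 gene lists were fixed before the files were opened: BAF subunits, VHL ligase, NOTCH targets, T-ALL transcription factors, T-lineage genes, cytokine receptors and migration, ribosome biogenesis, metabolic MYC targets, G1/S and replication, G2/M, apoptosis regulators, p53 targets and CDK inhibitors, interferon response, immediate early and AP-1 genes, NF-kB targets, hypoxia-inducible targets, ATF4 and unfolded protein response, heat shock, cholesterol synthesis, polycomb, mitochondrially encoded genes, and markers of B-lineage, myeloid, erythroid and stromal or epithelial cells. Lists with at least 5 tested members were tested with camera in limma 3.58.1 at the preset correlation of 0.01, with camera at an estimated correlation and with fry. Camera compares a list with the other genes, and fry tests it against no change. With an estimated correlation, camera takes its degrees of freedom from the few libraries of a fit, so it has little power here.

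The genes named in the text follow a rule written beforehand. In each line it takes SMARCA2, SMARCA4, PBRM1, MYC, NOTCH1, RUNX1 and MYB, the 8 largest rises and the 8 largest falls among called genes at a mean of 5 CPM or more with both treated libraries on the same side of both controls, and up to 2 rises and 2 falls with the smallest adjusted p per list. It also takes the 6 rises and 6 falls largest in both lines and the 5 genes of each sign with the largest difference between lines. Clone names, LOC, LINC, antisense and pseudogene names were left out. Genes outside the rule are marked in the text as chosen after their values were seen. Some results that the rule takes are not reported here.

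Before the main tests, the scripts were tested on simulated counts with 200 known changes, whose means and dispersions were taken from the real libraries. False calls were 4.47% of edgeR calls in DND-41, 7.89% in MOLT-4 and 5.07% for the difference. With DESeq2 they were 1.29%, 2.47% and 3.45%. At a log2 change of 0.5, edgeR recovered 68%, 76% and 30% of the changed genes. The simulated changes were balanced between rises and falls and far fewer than the calls in the real data. These rates may therefore not carry over to the real data. Alternatives fixed beforehand were DESeq2-type size factors, library size alone, no filter and a stricter filter on low counts, DESeq2 1.42.0, a replicate block, all 8 libraries in 1 fit, a threshold of 0.01, and leaving out each library in turn, where a lone library is assumed to vary like the others. Chosen after seeing the data were leaving out mitochondrially encoded genes, leaving out both MOLT-4 replicate 2 libraries, and keeping only genes at 1 CPM or more in both lines. Tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9. Groups of 2 leave few other splits of the libraries, which were not counted, and allow no test for an outlying library. Several genes have near-identical copies elsewhere in the genome, among them the mitochondrial genes and HSPA1A with HSPA1B, and their counts depend on how shared reads were treated.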

Results

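RNA was measured in 2 human T-cell acute lymphoblastic leukaemia (T-ALL) cell lines, DND-41 and MOLT-4, after 8 h with 100 nM ACBI-1 or with the solvent DMSO. ACBI-1 is a degrader that joins a ligand of the bromodomains of SMARCA2, SMARCA4 and PBRM1 to a ligand of the VHL ubiquitin ligase. SMARCA2 and SMARCA4 are the alternative ATPases of the BAF chromatin remodelling complexes, and PBRM1 is a subunit of one form of them. The comparison asks which transcripts change in each line within 8 h of treatment. There were 4 groups of 2 libraries, and library totals ran from 19860759 to 20239888 counts. Levels are CPM, counts scaled by effective library size, given as mean ± SD (n = 2 libraries), and log2 fold changes are ACBI-1 over DMSO, given ± SE (2 libraries against 2). At this depth 3 counts equal about 0.15 CPM. The labels do not say that the libraries came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

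The transcripts of the 3 proteins targeted by ACBI-1 changed by less than 2-fold in either line. The assay reads RNA, not the degraded protein. SMARCA4 rose in DND-41, from 484 ± 2.32 to 612 ± 14.3 CPM (log2 fold change 0.34 ± 0.06, adjusted p = 2.84e-04), and in MOLT-4, from 675 ± 24.2 to 771 ± 0.682 CPM (log2 fold change 0.19 ± 0.06, adjusted p = 0.0187). SMARCA2 was 69.9 ± 4.24 CPM with DMSO and 61.2 ± 4.38 with ACBI-1 in DND-41, where it fell (log2 fold change −0.19 ± 0.07, adjusted p = 0.0433). In MOLT-4 the SMARCA2 value was 0.14 ± 0.08 (adjusted p = 0.152). PBRM1 was at 0.06 ± 0.07 in DND-41 (adjusted p = 0.485), at 0.15, adjusted p = 0.0281 without ACBI-1 replicate 1 and −0.03, adjusted p = 0.686 without ACBI-1 replicate 2. It fell in MOLT-4 (−0.16 ± 0.06, adjusted p = 0.0288). The DND-41 SMARCA2 call ended without ACBI-1 replicate 1 (−0.12, adjusted p = 0.138) and without DMSO replicate 2 (−0.13, adjusted p = 0.389), with library size alone as the scale (−0.165, adjusted p = 0.136), with no filter (−0.203, adjusted p = 0.0874) and with DESeq2 (−0.194, adjusted p = 0.148). The MOLT-4 PBRM1 call ended without ACBI-1 replicate 2 (−0.08, adjusted p = 0.461) and without DMSO replicate 2 (−0.14, adjusted p = 0.0605), and with DESeq2 (−0.155, adjusted p = 0.113), no filter (−0.150, adjusted p = 0.0502) or all 8 libraries in 1 fit (−0.158, adjusted p = 0.0675). The MOLT-4 SMARCA4 call ended without ACBI-1 replicate 1 (0.20, adjusted p = 0.0575) or replicate 2 (0.20, adjusted p = 0.0663), and with library size alone as the scale (0.111, adjusted p = 0.398). Without both MOLT-4 replicate 2 libraries, in 1 fit with DND-41, SMARCA4 was at 0.218, adjusted p = 0.0788 and PBRM1 at −0.081, adjusted p = 0.616. Of the other BAF subunits, GLTSCR1L (BICRAL) rose from 38.3 ± 1.84 to 89.1 ± 1.48 CPM in DND-41 and from 6.93 ± 1.04 to 20.3 ± 0.0150 CPM in MOLT-4 (1.22 ± 0.07 and 1.55 ± 0.11). DPF3 fell in both lines (−1.58 ± 0.21 and −1.69 ± 0.15), as did BCL7A (−0.38 ± 0.06 and −0.77 ± 0.05). In DND-41, 8 of 27 BAF subunits rose and 6 fell (9 and 6 adjusted over the list alone, camera adjusted p = 0.381). In MOLT-4, 5 of 27 BAF subunits rose and 9 fell (6 and 10 adjusted over the list alone, camera adjusted p = 0.779). Of the VHL ligase genes, 1 of 5 rose in each line and none fell by the edgeR test. These were TCEB2 (ELOB) in DND-41 (0.19 ± 0.06) and RBX1 in MOLT-4 (0.31 ± 0.09), with camera adjusted p = 0.921 and 0.779, and the same counts adjusted over the list alone. The TCEB2 call ended without DMSO replicate 1 (0.21, adjusted p = 0.128) or DMSO replicate 2 (0.16, adjusted p = 0.271), with no filter (0.177, adjusted p = 0.0682) and with DESeq2 (0.186, adjusted p = 0.0612). The RBX1 call ended without DMSO replicate 1 (0.20, adjusted p = 0.0756), with library size alone (0.232, adjusted p = 0.0548), with DESeq2 (0.323, adjusted p = 0.0809) and without both replicate 2 libraries (0.399, adjusted p = 0.0901). Without 1 library, RBX1 passed as a fall in DND-41 (−0.34, adjusted p = 9.40e-04 without ACBI-1 replicate 1) and TCEB2 as a fall in MOLT-4 (−0.17, adjusted p = 0.0160 without DMSO replicate 1).

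In DND-41, NOTCH1, the receptor activated in many T-ALL cells, fell from 774 ± 6.52 to 332 ± 43.0 CPM (log2 fold change −1.22 ± 0.08, adjusted p = 1.36e-08). NOTCH3 fell from 511 ± 18.9 to 94.8 ± 10.4 CPM (log2 fold change −2.43 ± 0.07, adjusted p = 1.77e-11), and HES1, a transcriptional repressor induced by NOTCH signalling, fell from 85.6 ± 0.0370 to 30.8 ± 0.844 CPM (log2 fold change −1.47 ± 0.07, adjusted p = 5.09e-10). CXCR4, the chemokine receptor for CXCL12, fell from 223 ± 12.9 to 28.8 ± 1.31 CPM (log2 fold change −2.96 ± 0.07, adjusted p = 1.86e-12). In the other direction, EGR1, an immediate early transcription factor, rose from 37.5 ± 1.54 to 278 ± 12.6 CPM (log2 fold change 2.89 ± 0.07, adjusted p = 1.79e-12).

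Among 12 NOTCH pathway genes tested in DND-41, 1 rose, 9 fell and 2 did not pass the test (1 and 9 adjusted over the list alone). The median was −0.46, camera adjusted p = 5.69e-09, adjusted p = 0.237 with an estimated correlation. MYC, a NOTCH target and growth regulator, fell from 766 ± 5.93 to 569.8 ± 2.73 CPM (log2 fold change −0.43 ± 0.06, adjusted p = 3.72e-05). IL7R, the interleukin 7 receptor, rose (0.18 ± 0.06, adjusted p = 0.0215), a call that ended without DMSO replicate 1 (0.18, adjusted p = 0.246) or DMSO replicate 2 (0.18, adjusted p = 0.242). Among 23 transcription factors of T-ALL, 4 rose, 12 fell and 7 did not pass the test (4 and 13 adjusted over the list alone). The median was −0.43, camera adjusted p = 8.86e-06, adjusted p = 0.291 with an estimated correlation. TLX3, the homeobox oncogene of this line, fell from 326 ± 14.04 to 96.4 ± 3.26 CPM (log2 fold change −1.76 ± 0.06, adjusted p = 5.77e-11), and GFI1 fell by 1.49 on the log2 scale. TCF12 rose (0.63 ± 0.06), as did ARID5B (1.08 ± 0.23). RUNX1 and MYB did not pass the test (−0.09 ± 0.06, adjusted p = 0.300, and −0.15 ± 0.06, adjusted p = 0.0738). They passed without ACBI-1 replicate 2 for RUNX1 (−0.16, adjusted p = 0.00916) and without ACBI-1 replicate 1 for MYB (−0.22, adjusted p = 2.89e-04).

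Of 30 T-lineage genes tested in DND-41, 5 rose, 19 fell and 6 did not pass the test (5 and 19 adjusted over the list alone). The median was −0.48, camera adjusted p = 0.00387, adjusted p = 0.656 with an estimated correlation. The falls included UBASH3A, a phosphatase that limits T-cell receptor signalling (−1.79 ± 0.08), and the kinase ZAP70 (−0.92 ± 0.06). Of the T-cell receptor complex, CD3G rose from 323 ± 5.58 to 1008 ± 35.5 CPM (1.64 ± 0.06, adjusted p = 1.19e-10) and CD3E from 1455 ± 46.6 to 2279 ± 64.1 CPM (0.65 ± 0.07, adjusted p = 2.37e-06). Of 18 cytokine receptor and migration genes, 3 rose, 14 fell and 1 did not pass the test (3 and 14 adjusted over the list alone). The median was −0.95, camera adjusted p = 1.11e-10, adjusted p = 0.237 with an estimated correlation. TNFRSF1B, a receptor of tumour necrosis factor, fell from 12.01 ± 0.0690 to 1.17 ± 0.213 CPM (log2 fold change −3.35 ± 0.18, adjusted p = 3.44e-09), while SOCS1, an inhibitor of cytokine signalling, rose (0.45 ± 0.06).

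Interferon response and cholesterol synthesis were the lists that passed camera as higher in DND-41. Of 25 interferon response genes, 11 rose, 3 fell and 11 did not pass the test (12 and 5 adjusted over the list alone). The median was 0.06, camera adjusted p = 0.00555, adjusted p = 0.455 with an estimated correlation, and adjusted p = 0.0538 with fry, which tests a list against no change and not against other genes. USP18, a protease that limits interferon signalling, rose (1.11 ± 0.10), and OAS2 fell (−0.55 ± 0.08). Of 18 cholesterol synthesis genes, 11 rose, 4 fell and 3 did not pass the test (12 and 4 adjusted over the list alone). The median was 0.25, camera adjusted p = 0.0347, adjusted p = 0.455 with an estimated correlation. MVD and MVK, enzymes of the mevalonate pathway, rose (0.76 ± 0.06 and 0.61 ± 0.07), whereas FDFT1, which encodes squalene synthase, fell (−0.34 ± 0.06). The cholesterol call ended without DMSO replicate 1 (median 0.25, adjusted p = 0.0600) and without DMSO replicate 2 (median 0.21, adjusted p = 0.0538).

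The following lists did not pass camera in DND-41. Of the ribosome biogenesis genes, 11 of 28 tested rose and 0 fell (11 and 0 adjusted over the list alone, camera adjusted p = 0.159), with RRP12 at 0.56 ± 0.06. Among metabolic MYC targets, 4 of 24 tested rose and 9 fell (4 and 9 adjusted over the list alone, camera adjusted p = 0.636), and the falls included ODC1, the entry enzyme of polyamine synthesis (−0.81 ± 0.06), and the transferrin receptor gene TFRC (−0.65 ± 0.06). For G1/S and replication, 8 of 27 genes rose and 6 fell (8 and 6 adjusted over the list alone, camera adjusted p = 0.636), with MCM5 at 0.41 ± 0.06 and UHRF1 at −0.80 ± 0.06. For G2/M, 3 of 24 genes rose and 8 fell (3 and 8 adjusted over the list alone, camera adjusted p = 0.735), and CDC25B fell (−0.54 ± 0.06). Among apoptosis regulators, 7 of 17 tested rose and 7 fell (7 and 8 adjusted over the list alone, camera adjusted p = 0.921). BCL2, which blocks apoptosis, fell from 115 ± 3.06 to 57.4 ± 6.78 CPM (log2 fold change −1.01 ± 0.08, adjusted p = 8.47e-08), and BCL2L11 (BIM), which promotes it, rose from 58.7 ± 1.46 to 95.7 ± 4.57 CPM (log2 fold change 0.70 ± 0.07, adjusted p = 6.88e-07). CFLAR, an inhibitor of death receptor signalling, rose (1.049 ± 0.07). For p53 targets and CDK inhibitors, 5 of 18 genes rose and 3 fell (5 and 3 adjusted over the list alone, camera adjusted p = 0.636). For immediate early and AP-1 genes, 3 of 21 genes rose and 8 fell (3 and 9 adjusted over the list alone, camera adjusted p = 0.934), with EGR2 at 2.29 ± 0.18 and JUND at −0.76 ± 0.06. For NF-kB targets, 4 of 13 genes rose and 5 fell (4 and 5 adjusted over the list alone, camera adjusted p = 0.708), with TNF at −1.59 ± 0.09. For hypoxia-inducible targets, 1 of 18 genes rose and 8 fell (1 and 9 adjusted over the list alone, camera adjusted p = 0.159), with VEGFA at −1.003 ± 0.08. For ATF4 and unfolded protein response genes, 2 of 15 genes rose and 7 fell (2 and 7 adjusted over the list alone, camera adjusted p = 0.185), with DDIT4, an inhibitor of mTORC1, at 0.75 ± 0.08 and the chaperone gene HSPA5 at −0.68 ± 0.06. For heat shock genes, 0 of 12 genes rose and 5 fell (0 and 5 adjusted over the list alone, camera adjusted p = 0.636). For polycomb genes, 7 of 22 genes rose and 3 fell (7 and 3 adjusted over the list alone, camera adjusted p = 0.381), with PHF19 at −0.80 ± 0.06. Of the mitochondrially encoded genes, 0 of 13 tested rose and 0 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.662), with a median of 0.07.

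Among the largest rises in DND-41 under the fixed rule were SYT11, a synaptotagmin (4.21 ± 0.20), the cortactin gene CTTN (3.14 ± 0.10), EGR1, BSN (2.86 ± 0.12), ZNF341 (2.60 ± 0.09), CCDC121 (2.60 ± 0.21) and VPS37C (2.54 ± 0.10). The largest falls were APOBR (−3.93 ± 0.21), TNFRSF1B, the adhesion receptor gene EMR2 (−3.23 ± 0.13), RASSF2 (−3.15 ± 0.14), FGFR3 (−3.06 ± 0.16), CXCR4, PTPRCAP, which encodes a partner of the phosphatase CD45 (−2.93 ± 0.06), and the perforin gene PRF1 (−2.91 ± 0.25). By edgeR's quasi-likelihood test, 2807 genes rose and 3249 fell of 14008 tested at an adjusted p below 0.05. Of these, 278 rose and 898 fell by at least 2-fold. Without DMSO replicate 1, 1745 rose and 2557 fell, without DMSO replicate 2, 1817 and 2556, and with DESeq2, 1722 and 2335.

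**Figure D1:**
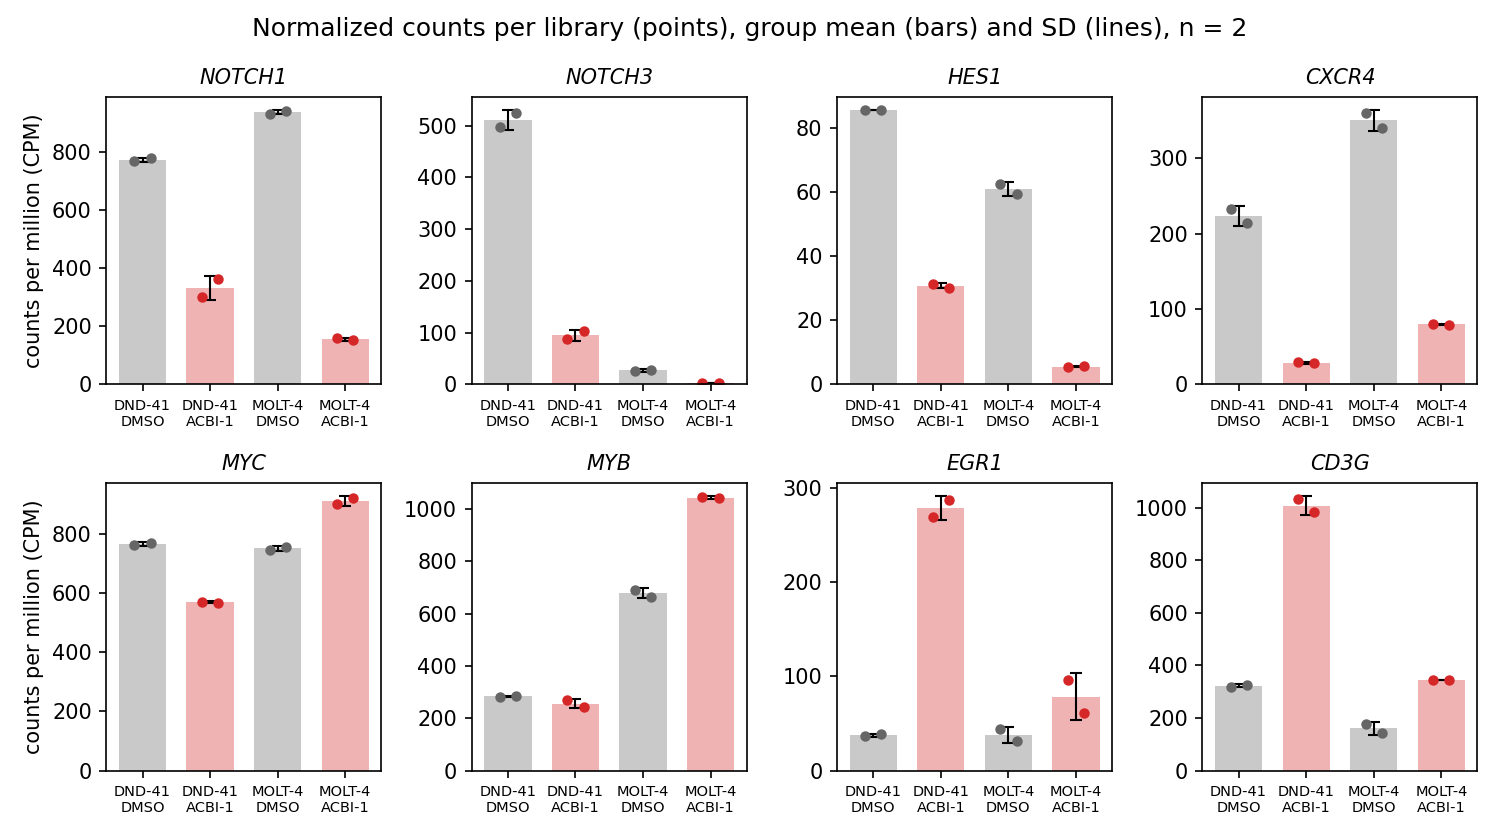
Normalized counts in CPM (y axis, from 0) of 8 genes in the 4 groups (x axis); points are libraries, bars group means and lines the SD (n = 2). NOTCH1 was at 774 CPM with DMSO and 332 with ACBI-1 in DND-41, and at 938 and 155 in MOLT-4, while MYC fell in DND-41 and rose in MOLT-4.

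In MOLT-4, 9 of 13 NOTCH pathway genes fell and 2 rose, 21 of 31 T-lineage genes fell and 4 rose, and 16 of 18 cholesterol synthesis genes rose and 0 fell. These lists passed camera at the preset correlation, and had adjusted p = 0.221, 0.221 and 0.378 with an estimated correlation. NOTCH1 fell from 938 ± 6.69 to 155 ± 4.53 CPM (log2 fold change −2.60 ± 0.06, adjusted p = 1.92e-16), and HES1 fell from 61.0 ± 2.20 to 5.53 ± 0.251 CPM (log2 fold change −3.46 ± 0.09, adjusted p = 3.59e-16). The chemokine receptor gene CCR9, which directs T cells to the gut, fell from 84.8 ± 5.17 to 7.35 ± 0.638 CPM (log2 fold change −3.53 ± 0.09, adjusted p = 2.40e-16). FGFR1, a fibroblast growth factor receptor, fell from 163 ± 2.06 to 12.4 ± 0.833 CPM (log2 fold change −3.72 ± 0.07, adjusted p = 6.69e-18). MYB, a transcription factor of blood progenitors, rose from 678 ± 19.6 to 1043 ± 4.42 CPM (log2 fold change 0.62 ± 0.07, adjusted p = 2.32e-07), and MVK rose from 21.8 ± 1.81 to 60.2 ± 2.42 CPM (log2 fold change 1.46 ± 0.08, adjusted p = 9.90e-12).

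Among 13 NOTCH pathway genes tested in MOLT-4, 2 rose, 9 fell and 2 did not pass the test (2 and 9 adjusted over the list alone). The median was −1.13, camera adjusted p = 6.79e-16, adjusted p = 0.221 with an estimated correlation. NOTCH3 fell (−3.65 ± 0.15). The rises were CCND3, which encodes cyclin D3 (0.32 ± 0.07), and MYC, which went from 752 ± 8.62 to 912 ± 15.5 CPM (log2 fold change 0.28 ± 0.06, adjusted p = 0.00156). With library size alone as the scale the MYC value was 0.20, adjusted p = 0.111. Among 26 T-ALL transcription factors, 6 rose, 14 fell and 6 did not pass the test (6 and 14 adjusted over the list alone). The median was −0.17, camera adjusted p = 0.0298, adjusted p = 0.677 with an estimated correlation. ERG rose from 102 ± 0.673 to 194 ± 6.55 CPM (0.92 ± 0.05), whereas FLI1, another ETS factor, and TOX fell (−1.22 ± 0.06 and −1.03 ± 0.06). RUNX1 did not pass the test (−0.08 ± 0.07, adjusted p = 0.386), and was at 0.00, adjusted p = 0.991 without ACBI-1 replicate 2. The T-ALL factors had adjusted p = 0.0611 with fry. Its camera call ended without ACBI-1 replicate 2 (median −0.17, adjusted p = 0.0903) and without both replicate 2 libraries, in 1 fit with DND-41 (median −0.29, adjusted p = 0.137).

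Of 31 T-lineage genes tested in MOLT-4, 4 rose, 21 fell and 6 did not pass the test (4 and 22 adjusted over the list alone). The median was −0.66, camera adjusted p = 1.73e-15, adjusted p = 0.221 with an estimated correlation. CD6 fell from 85.1 ± 1.499 to 11.6 ± 1.86 CPM (−2.87 ± 0.09) and UBASH3A fell as well (−1.89 ± 0.06). CD3G rose (1.11 ± 0.07), as did PTPRC, which encodes CD45 (0.40 ± 0.06). Of 19 cytokine receptor and migration genes, 1 rose, 14 fell and 4 did not pass the test (1 and 14 adjusted over the list alone). The median was −0.99, camera adjusted p = 6.04e-13, adjusted p = 0.221 with an estimated correlation. ITGAL, an integrin subunit of T cells, fell from 160.4 ± 1.27 to 24.8 ± 2.94 CPM (log2 fold change −2.69 ± 0.07, adjusted p = 2.40e-16), and S1PR1, a receptor for exit from lymphoid tissue, rose (0.67 ± 0.08).

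Cholesterol synthesis was the list with the largest share of rises in MOLT-4. Of its 18 tested genes, 16 rose, 0 fell and 2 did not pass the test (17 and 0 adjusted over the list alone). The median was 0.92, camera adjusted p = 1.59e-21, adjusted p = 0.378 with an estimated correlation. DHCR7, the last enzyme of one branch of the pathway, rose from 99.8 ± 1.51 to 227 ± 7.23 CPM (log2 fold change 1.19 ± 0.05, adjusted p = 9.28e-13). Of 28 ribosome biogenesis genes, 14 rose, 0 fell and 14 did not pass the test (14 and 0 adjusted over the list alone). The median was 0.15, camera adjusted p = 0.0114, adjusted p = 0.537 with an estimated correlation, with RRP12 at 0.39 ± 0.05 and BYSL at 0.49 ± 0.07. With library size alone as the scale the ribosome biogenesis median was 0.065, adjusted p = 0.0450. Of 28 G1/S and replication genes, 16 rose, 3 fell and 9 did not pass the test (17 and 3 adjusted over the list alone). The median was 0.16, camera adjusted p = 0.0298, adjusted p = 0.392 with an estimated correlation. CCNE2, a cyclin of the entry into S phase, rose (0.77 ± 0.07), and UHRF1 fell (−0.72 ± 0.06). Of 24 G2/M genes, 0 rose, 14 fell and 10 did not pass the test (1 and 15 adjusted over the list alone). The median was −0.23, camera adjusted p = 0.0116, adjusted p = 0.467 with an estimated correlation, with CCNB2 at −0.45 ± 0.05 and PLK1 at −0.38 ± 0.05. Of 16 ATF4 and unfolded protein response genes, 2 rose, 10 fell and 4 did not pass the test (3 and 10 adjusted over the list alone). The median was −0.33, camera adjusted p = 4.65e-05, adjusted p = 0.221 with an estimated correlation. HSPA5, the main chaperone of the endoplasmic reticulum, fell from 547 ± 11.1 to 209 ± 15.7 CPM (log2 fold change −1.39 ± 0.06, adjusted p = 7.53e-13), XBP1 fell by 1.43 and DDIT4 fell from 19.4 ± 0.395 to 3.57 ± 0.236 CPM (log2 fold change −2.44 ± 0.12, adjusted p = 3.58e-12). The G1/S call ended without ACBI-1 replicate 1 (median 0.14, adjusted p = 0.0570) and with library size alone as the scale (median 0.08, adjusted p = 0.103).

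Mitochondrially encoded transcripts took 23.0 ± 2.36% of counts in the MOLT-4 ACBI-1 libraries and 16.7 ± 3.23% in the DMSO libraries, against 13.6 ± 2.65% and 12.7 ± 0.719% in DND-41. Of the 13 genes tested in MOLT-4, 11 rose, 0 fell and 2 did not pass the test (11 and 0 adjusted over the list alone). The median was 0.65, camera adjusted p = 1.37e-04, adjusted p = 0.637 with an estimated correlation, and adjusted p = 0.159 with fry. MT-ND6 rose (1.09 ± 0.14), as did MT-ATP8 (1.21 ± 0.17, 0.77, adjusted p = 6.83e-10 without ACBI-1 replicate 2). The 2 MOLT-4 DMSO libraries were themselves at 19.0% and 14.4%. With both MOLT-4 replicate 2 libraries left out of a fit with DND-41, chosen after seeing the data, the list's median was 0.25, adjusted p = 0.158, MT-ND6 was at 0.57, adjusted p = 0.0754 and MT-ATP8 at 0.564, adjusted p = 0.0507. Without DMSO replicate 2 alone it was 0.39, adjusted p = 4.24e-05.

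The lists that did not pass camera in MOLT-4 were the following. For metabolic MYC targets, 15 of 24 genes rose and 4 fell (15 and 4 adjusted over the list alone, camera adjusted p = 0.0802), with HK2 at 0.43 ± 0.05 and ODC1 at −0.84 ± 0.06. Among apoptosis regulators, 3 of 18 tested rose and 9 fell (3 and 9 adjusted over the list alone, camera adjusted p = 0.229), with BCL2L11 at 0.78 ± 0.06, BCL2 at −0.77 ± 0.09 and the death receptor gene FAS at −1.40 ± 0.12. For p53 targets and CDK inhibitors, 3 of 19 genes rose and 7 fell (3 and 7 adjusted over the list alone, camera adjusted p = 0.568), with CDKN2D at −0.94 ± 0.08. For interferon response, 9 of 25 genes rose and 5 fell (9 and 5 adjusted over the list alone, camera adjusted p = 0.249), with IRF7 at −1.61 ± 0.24. For immediate early and AP-1 genes, 4 of 23 genes rose and 13 fell (4 and 13 adjusted over the list alone, camera adjusted p = 0.505), with EGR2 at 2.55 ± 0.28 and NR4A3 at 3.02 ± 0.31. For NF-kB targets, 3 of 12 genes rose and 4 fell (4 and 4 adjusted over the list alone, camera adjusted p = 0.670), with LTB, a cytokine of lymphoid organ formation, at −2.98 ± 0.20. For hypoxia-inducible targets, 5 of 18 genes rose and 6 fell (5 and 6 adjusted over the list alone, camera adjusted p = 0.615), with the glucose transporter gene SLC2A3 at −2.47 ± 0.17. For heat shock, 0 of 12 genes rose and 6 fell (0 and 6 adjusted over the list alone, camera adjusted p = 0.533), with BAG3 at −0.56 ± 0.09. For polycomb, 4 of 22 genes rose and 5 fell (4 and 5 adjusted over the list alone, camera adjusted p = 0.904), with PHF19 at −0.53 ± 0.05 and EZH1 at 0.50 ± 0.06. Median, mean and camera direction differed in sign in DND-41 for BAF subunits, VHL ligase, metabolic MYC targets, apoptosis regulators and p53 targets, and in MOLT-4 for BAF subunits, VHL ligase and polycomb, none of which passed.

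The largest rises in MOLT-4 under the fixed rule were GPR17, a receptor of the nervous system (4.08 ± 0.19), the pseudokinase gene TRIB1 (3.20 ± 0.19), SYT11 (3.03 ± 0.11), PTK2, which encodes focal adhesion kinase (2.98 ± 0.16), BSN (2.60 ± 0.08), the thyrotropin receptor gene TSHR (2.40 ± 0.07), DAB1 (2.26 ± 0.14) and LZTS3 (2.25 ± 0.16). The largest falls were TMC8 (−5.30 ± 0.12), SEMA7A (−4.92 ± 0.20), FGFRL1 (−4.66 ± 0.17), TMC6 (−4.44 ± 0.13), the cholesterol exporter gene ABCA1 (−3.91 ± 0.13), PDCD1, which encodes the immune checkpoint receptor PD-1 (−3.89 ± 0.20), FGFR1 and PRDM16 (−3.70 ± 0.14). By edgeR's quasi-likelihood test, 2948 genes rose and 3477 fell of 14239 tested at an adjusted p below 0.05, and 281 rose and 1200 fell by at least 2-fold. With library size alone as the scale, 1781 rose and 3922 fell, a share of rises of 31.2% against 45.9%. DESeq2 called 4032 genes, 1765 higher and 2267 lower. All 8 libraries in 1 fit gave 6197 calls, and such a fit without both MOLT-4 replicate 2 libraries gave 3589, with the 2 lone MOLT-4 libraries assumed to vary like the DND-41 ones.

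**Figure D2:**
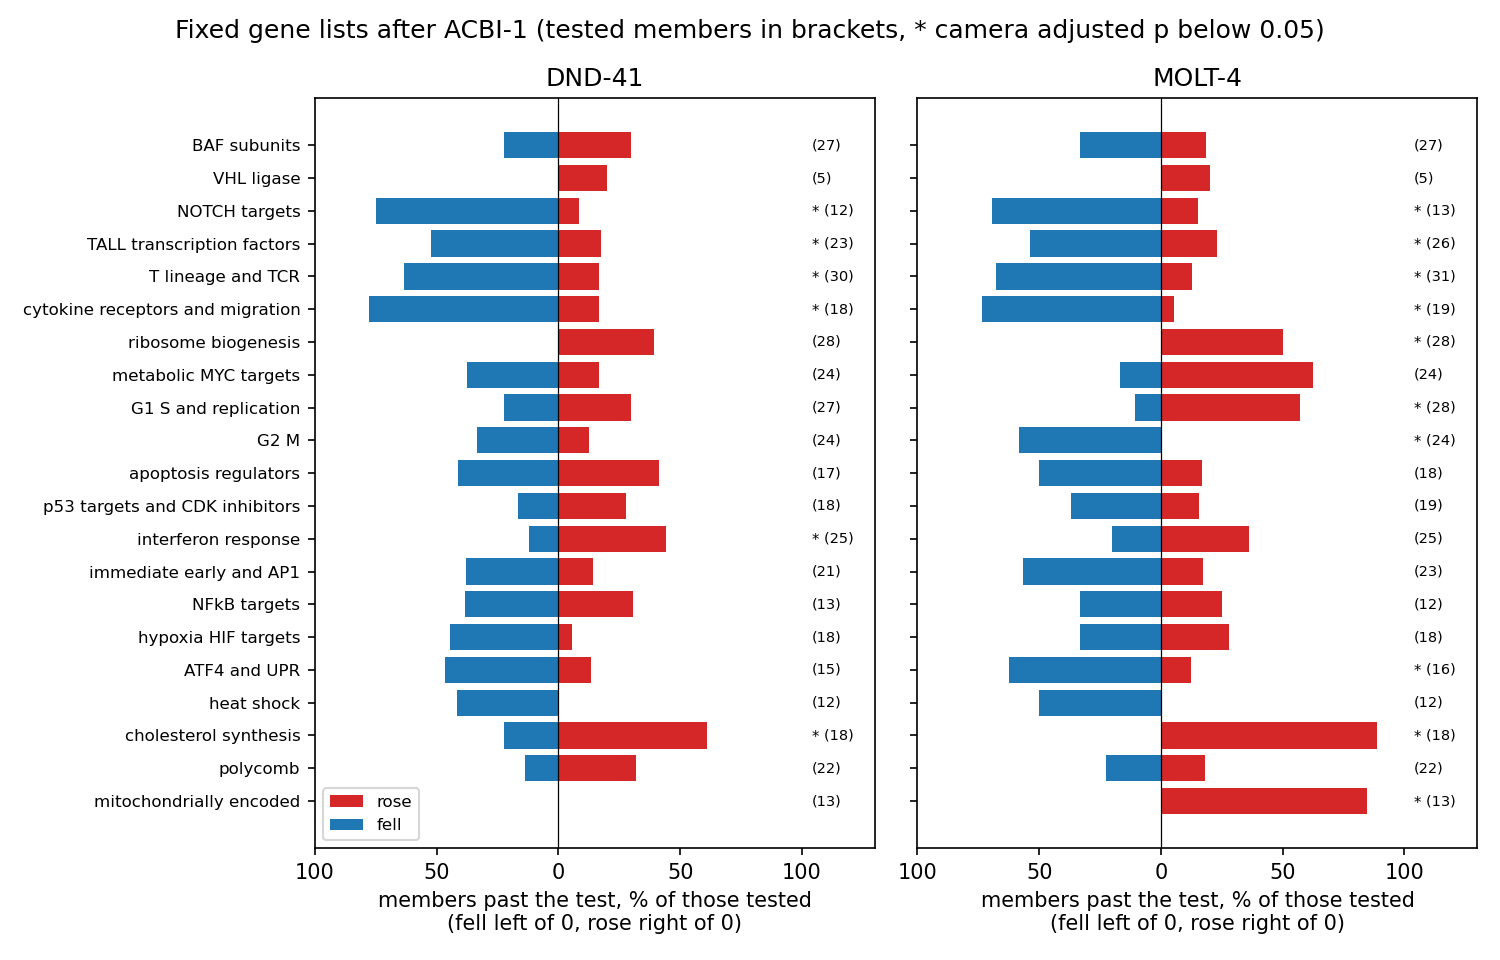
Share of tested members of each fixed list (y axis) that rose (red, right of 0) or fell (blue, left of 0) after ACBI-1, in percent (x axis), in DND-41 and MOLT-4; the number tested is in brackets and a star marks a camera adjusted p below 0.05 at the preset correlation. Cholesterol synthesis had 16 rises of 18 in MOLT-4 and 11 of 18 in DND-41, and NOTCH targets 9 falls of 13 and 9 of 12.

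Many genes moved in the same direction in both lines. Under the fixed rule for shared changes, the rises were SYT11, BSN, GPR17 (2.44 ± 0.17 in DND-41 and 4.08 ± 0.19 in MOLT-4), ZNF341 (2.60 ± 0.09 and 2.21 ± 0.08), CTTN (3.14 ± 0.10 and 1.94 ± 0.14) and DISP2 (2.32 ± 0.14 and 1.85 ± 0.16). The shared falls were RASSF2 (−3.15 ± 0.14 and −3.08 ± 0.16), PTPRCAP (−2.93 ± 0.06 and −2.79 ± 0.06), TMC8 (−2.88 ± 0.07 and −5.30 ± 0.12), its neighbour TMC6 (−2.84 ± 0.11 and −4.44 ± 0.13), KCNA6 (−2.495 ± 0.21 and −3.17 ± 0.19) and WT1, a transcription factor expressed in leukaemia (−2.69 ± 0.12 and −3.002 ± 0.09). TMC6 and TMC8 lie side by side, and the strand setting of the counting is not given in the sources used here, so part of their counts could be shared.

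Of 12859 genes tested in both lines, 1546 rose in both where independent lists would share 591.2, and 2011 fell in both where they would share 692.0. Fisher's exact test, one-sided, gave log10 p of −474 and −829. It takes genes as independent, which they are not, and does not measure the spread between libraries. Opposite calls numbered 98 genes that rose in DND-41 and fell in MOLT-4, and 118 the other way, against 630.9 and 648.5 for independent lists. Across genes, which are not independent replicates, log2 fold changes of the lines had Pearson's r = 0.677 and Spearman's rho = 0.621. The lines have separate DMSO libraries, so no control is shared. DESeq2 calls gave 918 shared rises and 1323 shared falls.

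**Figure D3:**
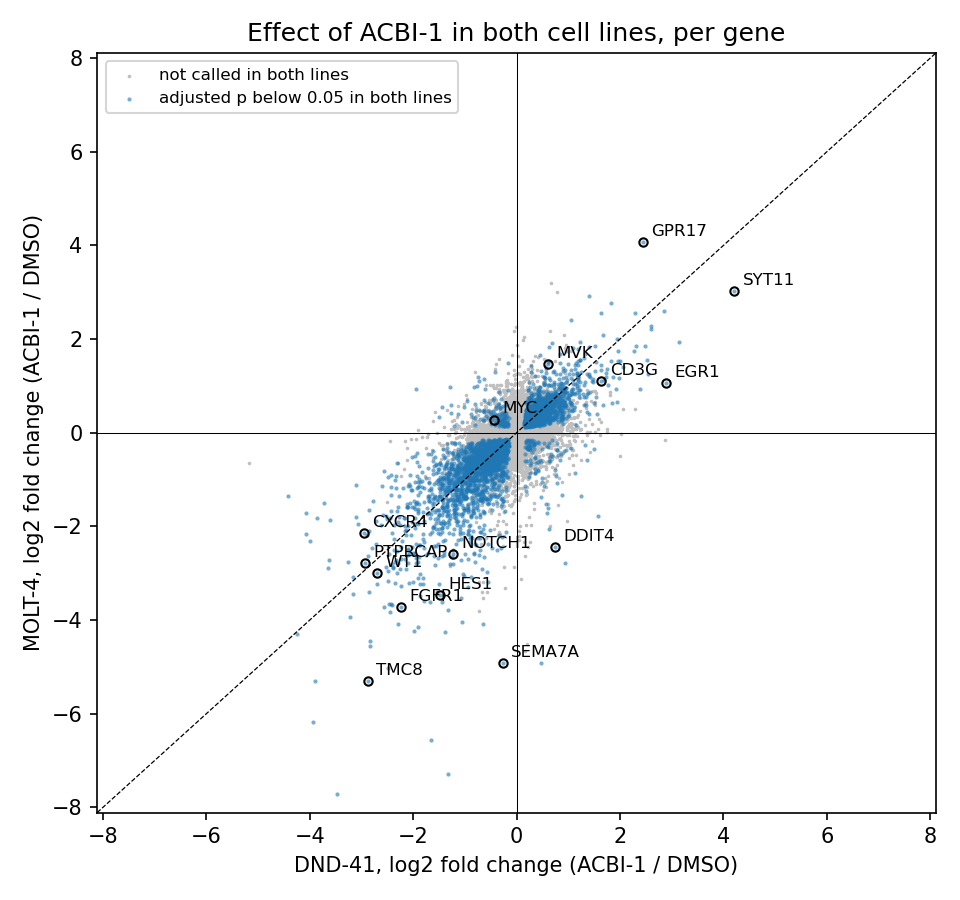
Log2 fold change of each gene after ACBI-1 in MOLT-4 (y axis) against DND-41 (x axis), for 12859 genes tested in both; blue points passed an adjusted p of 0.05 in both lines, the dashed line marks equal effects and circles mark genes named in the text. WT1 and PTPRCAP lie near the diagonal away from 0, and SEMA7A and DDIT4 lie away from it.

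The difference of the ACBI-1 effect between the lines was tested as the MOLT-4 log2 fold change minus that of DND-41 in a fit of all 8 libraries. The NOTCH1 fall was larger in MOLT-4 (difference −1.36 ± 0.10, adjusted p = 4.19e-08), as were those of HES1 (−1.97 ± 0.11, adjusted p = 9.47e-10) and NOTCH3 (−1.21 ± 0.20). MYC and MYB differed in the other direction (0.72 ± 0.08, adjusted p = 5.38e-06, and 0.78 ± 0.09, adjusted p = 4.60e-06). DDIT4 rose in DND-41 and fell in MOLT-4 (difference −3.17 ± 0.15, adjusted p = 1.08e-10).

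Among fixed list members, 12 fell in DND-41 and rose in MOLT-4, and 5 did the reverse. All 17 passed the test of the difference, but both calls held without each library in turn for only 6 of the 12 and 1 of the 5. The genes of this paragraph that follow were chosen after their values were seen. The first kind included EGLN3, a HIF prolyl hydroxylase (−1.28 ± 0.13 and 0.98 ± 0.29), TERT, the catalytic subunit of telomerase (−1.27 ± 0.14 and 0.58 ± 0.10) and ETS1 (−0.79 ± 0.06 and 0.48 ± 0.06). The second included SATB1, a chromatin organiser of thymocytes (0.27 ± 0.06 and −0.69 ± 0.05). The EGLN3 call in MOLT-4 ended without ACBI-1 replicate 1 (0.98, adjusted p = 0.0562), and the SATB1 call in DND-41 without DMSO replicate 1 (0.24, adjusted p = 0.0775).

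Of the fixed lists, 12 passed camera for the difference. Cholesterol synthesis had the smallest p, with 17 of 18 genes higher in the MOLT-4 effect and 1 lower (median 0.66, camera adjusted p = 1.93e-26, adjusted p = 0.0801 with an estimated correlation, 17 and 1 adjusted over the list alone). FDFT1 differed by 0.94 ± 0.10. Lower in the MOLT-4 effect were NOTCH targets (7 lower and 3 higher of 13, 7 and 3 over the list alone, median −0.57, camera adjusted p = 8.66e-09, adjusted p = 0.0660 with an estimated correlation) and T-lineage genes (13 and 4 of 31, 15 and 5 over the list alone, median −0.34, camera adjusted p = 8.27e-04, adjusted p = 0.190 with an estimated correlation), with CD3E at −0.69 ± 0.10. So were ATF4 and unfolded protein response genes (6 and 1 of 16, 7 and 1 over the list alone, median −0.28, camera adjusted p = 5.88e-06, adjusted p = 0.0801 with an estimated correlation) and interferon response genes (6 and 0 of 25, 9 and 1 over the list alone, median −0.14, camera adjusted p = 0.00902, adjusted p = 0.330 with an estimated correlation). NF-kB targets (5 and 0 of 14, 5 and 0 over the list alone, median −0.20, camera adjusted p = 0.00735, adjusted p = 0.156 with an estimated correlation), apoptosis regulators (6 and 0 of 18, 9 and 1 over the list alone, median −0.24, camera adjusted p = 0.0146, adjusted p = 0.156 with an estimated correlation) and G2/M genes (6 and 0 of 24, 6 and 0 over the list alone, median −0.14, camera adjusted p = 0.00902, adjusted p = 0.432 with an estimated correlation) were also lower. Without 1 library the NOTCH median was −0.92, adjusted p = 3.33e-08 (DND-41 DMSO replicate 1) and −0.90, adjusted p = 6.74e-04 (MOLT-4 ACBI-1 replicate 1), the NF-kB median −0.13, adjusted p = 0.0125 (DND-41 ACBI-1 replicate 1) and −0.08, adjusted p = 0.00831 (DND-41 DMSO replicate 1), and the interferon median −0.08, adjusted p = 0.0433 (DND-41 ACBI-1 replicate 1). The G2/M call ended without DND-41 ACBI-1 replicate 1 (median −0.061, adjusted p = 0.0712), and the list had adjusted p = 0.0506 with fry. With library size alone as the scale the medians were −0.26, adjusted p = 7.49e-04 for G2/M, −0.36, adjusted p = 0.00746 for apoptosis, −0.27, adjusted p = 0.00443 for interferon and −0.32, adjusted p = 0.00746 for NF-kB. Without both MOLT-4 replicate 2 libraries they were −0.17, adjusted p = 0.0579 for NF-kB and −0.18, adjusted p = 0.0122 for ATF4 and unfolded protein response genes.

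Higher in the MOLT-4 effect were metabolic MYC targets (9 higher and 0 lower of 24, 10 and 0 over the list alone, median 0.17, camera adjusted p = 1.03e-04, adjusted p = 0.156 with an estimated correlation), with HK2 at 0.65 ± 0.08. Their median was 0.11, adjusted p = 0.00193 without MOLT-4 DMSO replicate 2, 0.047, adjusted p = 0.00479 with library size alone as the scale and 0.090, adjusted p = 0.0122 without both MOLT-4 replicate 2 libraries. G1/S genes passed camera as higher with TMM scaling (5 and 0 of 28, 6 and 0 over the list alone, median 0.08, camera adjusted p = 0.0162, adjusted p = 0.372 with an estimated correlation). With library size alone the G1/S call ended and the median turned to −0.039, adjusted p = 0.199, and without mitochondrially encoded genes it was 0.055, adjusted p = 0.0348. Mitochondrially encoded genes were higher too (6 and 0 of 13, 8 and 0 over the list alone, median 0.58, camera adjusted p = 7.69e-05, adjusted p = 0.432 with an estimated correlation), with a median of 0.14, adjusted p = 0.211 without both MOLT-4 replicate 2 libraries, and adjusted p = 0.224 with fry. The median was 0.88, adjusted p = 2.86e-10 without DND-41 ACBI-1 replicate 1, 0.92, adjusted p = 3.72e-08 without MOLT-4 DMSO replicate 1 and 0.36, adjusted p = 0.00689 without MOLT-4 DMSO replicate 2. T-ALL transcription factors had 8 higher and 5 lower of 28 (11 and 6 over the list alone, median 0.01, camera adjusted p = 0.0433, adjusted p = 0.432 with an estimated correlation). That call ended without DND-41 ACBI-1 replicate 1 (median −0.02, adjusted p = 0.102), MOLT-4 ACBI-1 replicate 1 (median 0.07, adjusted p = 0.273), MOLT-4 DMSO replicate 1 (median 0.10, adjusted p = 0.0733) and MOLT-4 DMSO replicate 2 (median −0.05, adjusted p = 0.200). The list had adjusted p = 0.0714 with fry. The camera call also ended with library size alone (median −0.116, adjusted p = 0.115) and without both MOLT-4 replicate 2 libraries (median 0.02, adjusted p = 0.144), so the median had no stable direction. The other lists did not pass, with camera adjusted p of 0.591 for BAF subunits, 0.835 for VHL ligase, 0.220 for cytokine receptors, 0.199 for ribosome biogenesis, 0.0828 for p53 targets, 0.210 for immediate early genes, 0.591 for hypoxia targets, 0.915 for heat shock, 0.298 for polycomb and 0.635 for B-lineage markers.

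The fixed rule named for the difference ARHGAP32, DAB2IP, MLK4, BEGAIN, SLC17A9, CHST15, RGS1, ZP1, SEMA7A and FGFRL1. The first 7 had both group means below 1 CPM in 1 line, so their fitted differences rest on few counts and are not given. ZP1 was at 1.25 ± 0.363 and 0.179 ± 0.0410 CPM in MOLT-4, so its difference is not given either. Among genes at 1 CPM or more in both lines, a limit chosen after the values were seen, the same rule named FGFRL1 (−4.80 ± 0.37), SEMA7A (−4.64 ± 0.22), DDIT4 and TBKBP1 (−3.07 ± 0.39) among those lower in MOLT-4. It named EGLN3, TERT, XYLB (1.998 ± 0.19), STAT5A (1.996 ± 0.20) and KCNJ11 (1.96 ± 0.27) as higher. The values given are from the fit without that limit. FGFRL1 was at 0.9 to 1.32 CPM in the DND-41 libraries, and TBKBP1 at 0.45 and 0.16 CPM in the MOLT-4 ACBI-1 libraries. EGLN3 and KCNJ11 were at 0.99 to 2.2 and 0.94 to 2.75 CPM in MOLT-4. SEMA7A was at 0.55 and 0.52 CPM in the MOLT-4 ACBI-1 libraries, and STAT5A at 1.48 and 2.14 CPM in the DND-41 ACBI-1 libraries. The differences of these genes therefore also rest on low counts. Over 15498 genes, edgeR's quasi-likelihood test of the difference called 1112 higher and 956 lower in the MOLT-4 effect. With library size alone as the scale, 499 were higher and 1411 lower, a share of higher calls of 26.1% against 53.8%, since that scale moved the median of all genes by −0.12. DESeq2 called 1307 genes, and 944 were called with both MOLT-4 replicate 2 libraries left out, which leaves 1 MOLT-4 library per treatment. Leaving out 1 library gave as few as 1367 (MOLT-4 ACBI-1 replicate 1) and 1368 (DND-41 DMSO replicate 2).

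**Figure D4:**
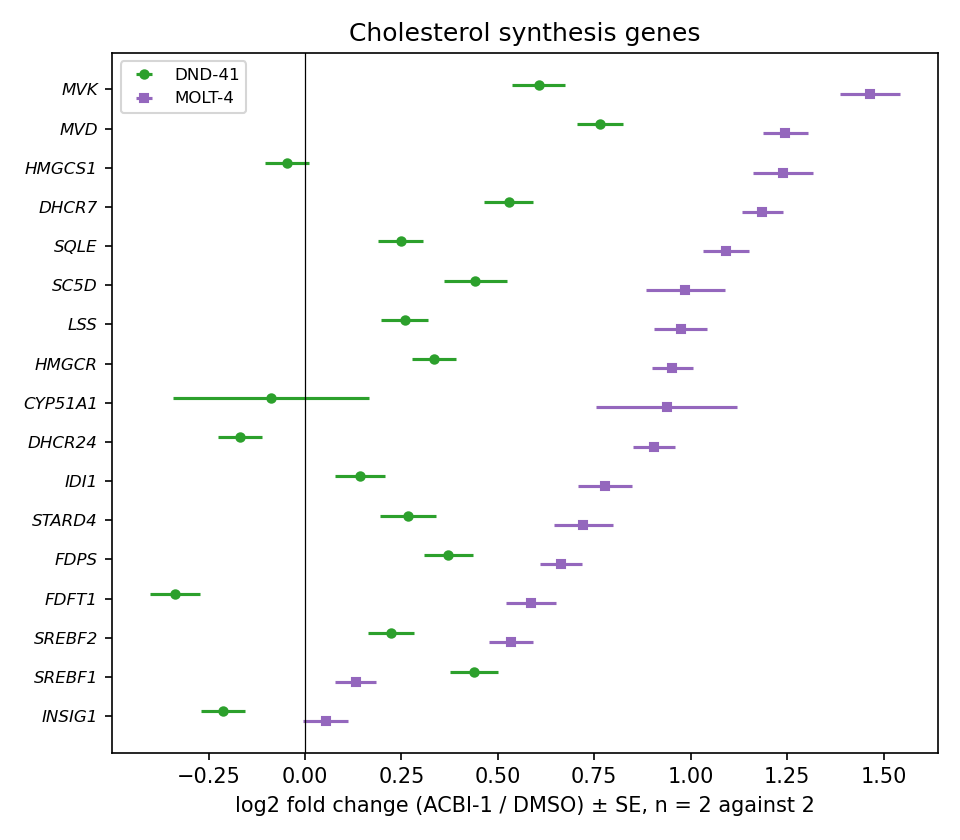
Log2 fold change ± SE (x axis) of cholesterol synthesis genes (y axis, ordered by the MOLT-4 value) in DND-41 (green circles) and MOLT-4 (purple squares), 2 libraries against 2. MVK was at 1.46 in MOLT-4 and 0.61 in DND-41, and FDFT1 at 0.59 and −0.34.

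In the authors' deposited table for DND-41, 4061 genes had an adjusted p below 0.05, and all had the sign of ACBI-1 over DMSO in the counts. In the authors' deposited table for MOLT-4, 4035 genes did, and 0% had that sign. NOTCH1 is at −1.22 in the authors' deposited table for DND-41 and at 2.59 in the authors' deposited table for MOLT-4, where the counts per library gave −2.60. Across genes Pearson's r between the fold changes computed here and those of the authors' deposited table was 0.9999 for DND-41 and −0.9997 for MOLT-4. All MOLT-4 directions given here were computed from the counts by their labels.

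Markers of other lineages were measured in the same libraries. Of the B-lineage markers, CD79A, a chain of the B-cell receptor complex, was at 1662 ± 11.8 CPM in DND-41 with DMSO and fell with ACBI-1 (−0.71 ± 0.06). BLK fell in both lines (−0.75 ± 0.07 and −0.85 ± 0.06), and all 4 B-lineage markers tested fell in each line (4 adjusted over the list alone). No myeloid marker reached the filter for testing, and their summed level was between 0.15 and 0.75 CPM. Of the erythroid markers, EPOR was tested in both lines and KLF1 in MOLT-4, and none passed the edgeR test at an adjusted p of 0.05. Stromal and epithelial markers summed to at most 0.20 CPM in each DND-41 library. In MOLT-4 they summed to 3.87 and 70.5 CPM in DMSO replicates 1 and 2, and to 0.75 and 15.1 CPM in ACBI-1 replicates 1 and 2. COL1A1, a chain of type I collagen, made up most of this signal, at 52.5 CPM in DMSO replicate 2 and 10.7 CPM in ACBI-1 replicate 2. Of 4 such markers tested in MOLT-4, 3 fell (4 adjusted over the list alone), COL1A1 among them (−2.38 ± 0.82, adjusted p = 0.0241). Without DMSO replicate 2 the COL1A1 value was 1.35, adjusted p = 5.56e-07, which compares both ACBI-1 libraries with DMSO replicate 1. It was −1.35, adjusted p = 2.77e-28 without ACBI-1 replicate 1 and −12.14, adjusted p = 1.29e-165 without ACBI-1 replicate 2, where the remaining ACBI-1 library held 0 counts. Without both replicate 2 libraries, in 1 fit with DND-41, it was −8.505, adjusted p = 9.71e-04, and DESeq2 gave −2.34, adjusted p = 0.731.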

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

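The tests of a swap of the MOLT-4 labels, of the scale of the libraries and of the stromal transcripts were chosen only after the results were seen. These results were picked out because the ACBI-1 effect differed between the 2 cell lines by the interaction test. Among genes whose effects from all libraries the text gives in both lines or as a difference, the MOLT-4 log2 fold change minus that of DND-41 was −4.80 for FGFRL1, −4.64 for SEMA7A, −3.17 for DDIT4, −3.07 for TBKBP1, −2.41 for TMC8, −1.97 for HES1, −1.59 for TMC6, −1.36 for NOTCH1, −1.27 for LCP2, −1.21 for NOTCH3, −1.19 for CTTN, −1.17 for SYT11, −0.94 for SATB1, −0.89 for CD247, −0.69 for CD3E, −0.69 for HSPA5, −0.52 for CD3G, −0.39 for CD7 and −0.37 for BCL7A. It was above 0 for the others, at 0.29 for PHF19, 0.35 for SMARCA2, 0.65 for HK2, 0.72 for MYC, 0.79 for MYB, 0.88 for MVK, 0.94 for FDFT1, 1.04 for MT-ND6, 1.29 for ETS1, 1.65 for GPR17, 1.87 for TERT, 1.96 for KCNJ11, 1.996 for STAT5A, 1.998 for XYLB and 2.27 for EGLN3. Leaving out 1 library ended the call or moved the value by over 1.5 times for CD3G (−0.34 without MOLT-4 DMSO replicate 1), CD7 (−0.37 without DND-41 DMSO replicate 1, −0.39 without DND-41 DMSO replicate 2, −0.28 without MOLT-4 ACBI-1 replicate 1), MT-ND6 (0.814 without DND-41 DMSO replicate 2, 0.708 without MOLT-4 ACBI-1 replicate 2, 0.835 without MOLT-4 DMSO replicate 2), PHF19 (0.28 without DND-41 DMSO replicate 2, 0.28 without MOLT-4 ACBI-1 replicate 1, 0.26 without MOLT-4 DMSO replicate 2), SMARCA2 (0.29 without DND-41 ACBI-1 replicate 1, 0.29 without DND-41 DMSO replicate 2, 0.40 without MOLT-4 ACBI-1 replicate 1, 0.31 without MOLT-4 ACBI-1 replicate 2, 0.30 without MOLT-4 DMSO replicate 1, 0.38 without MOLT-4 DMSO replicate 2) and SYT11 (−0.80 without DND-41 DMSO replicate 2). Among the fixed lists that passed camera at the preset correlation, the median difference was −0.57 for NOTCH targets, 0.006 for T-ALL transcription factors, −0.34 for T-lineage genes, 0.17 for metabolic MYC targets, 0.084 for G1/S and replication, −0.14 for G2/M, −0.24 for apoptosis regulators, −0.14 for interferon response, −0.20 for NF-kB targets, −0.28 for ATF4 and unfolded protein response, 0.66 for cholesterol synthesis and 0.58 for mitochondrially encoded genes. None passed with an estimated correlation (adjusted p from 0.0660 to 0.432), and with library size alone the T-ALL factor and G1/S calls ended and their medians turned to −0.116 and −0.039. Leaving out 1 library ended the T-ALL factor call (medians from −0.050 to 0.102) and the G2/M call (−0.061), and moved the median by over 1.5 times for NOTCH targets, metabolic MYC targets, interferon response, NF-kB targets and mitochondrially encoded genes. Without both MOLT-4 replicate 2 libraries the T-ALL factor, NF-kB and mitochondrial calls ended.

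The deposited MOLT-4 fold changes had the opposite sign to the counts. If the treatment labels of the MOLT-4 count columns were swapped, genes called in both lines would mostly move in opposite directions, but 94.3% had the same sign. This argues against such a swap. By the labels of the counts, all 4035 genes called in the deposited MOLT-4 table therefore had the sign of DMSO over ACBI-1. The headers do not state the contrast, but both deposited tables are named DMSO vs ACBI. Read as DMSO over ACBI-1, that name matches the MOLT-4 signs and not the DND-41 signs. How the signs came to differ between the tables was not tested.

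Falls of at least 2-fold outnumbered rises of that size, 898 to 278 in DND-41 and 1200 to 281 in MOLT-4. A shift of all log2 fold changes would have to reach 0.307 in DND-41 and 0.398 in MOLT-4 to make them equal. The scalings tried differed by at most 0.025 and 0.08, so the choice among them does not account for the imbalance. All of them assume that most genes or the total stay unchanged, so they cannot tell whether RNA per cell changed. After a trend on GC content and length was removed, the ratio of falls to rises went from 3.23 to 2.11 in DND-41 and from 4.27 to 2.49 in MOLT-4, so this trend could account for part of it and not for all. An early loss of transcription after the BAF ATPases are degraded stays open and was untested. No spike-in is named in the sources used here, and no group had an inactive control compound.

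Stromal transcripts were present in the MOLT-4 replicate 2 libraries. Of 72 genes picked as higher in DMSO replicate 2 than in DMSO replicate 1, 67 (93.1%, 95% interval 84.5 to 97.7 by the exact binomial test) were also higher in ACBI-1 replicate 2 than in ACBI-1 replicate 1, against 48.8% of all genes at 20 counts or more. The interval takes the genes as independent, which they are not. It does not measure the spread between libraries, as 1 ACBI-1 library stands against 1. RNA or reads of another cell type shared by both replicate 2 libraries could give this. A fall of these transcripts with ACBI-1 in the MOLT-4 cells and a smaller share of such RNA in the ACBI-1 libraries cannot be told apart, as 1 library stands against 1 within each replicate number. Of the 56 picked genes that differed between the replicate 1 libraries, 80.4% were lower with ACBI-1, and 18 of the 72 were called as falling. The source of the signal stays open.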

How the results depend on the processing

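Leaving out both MOLT-4 replicate 2 libraries, leaving out mitochondrially encoded genes and keeping only genes at 1 CPM or more in both lines were tests chosen only after the results were seen. Of the counts of calls under alternatives, 115 stayed within 1.5 times the main count and 11 did not. For MOLT-4, 6425 genes were called, against 4032 with DESeq2 and 3589 without both replicate 2 libraries in 1 fit with DND-41, where each lone MOLT-4 library is assumed to vary like the DND-41 ones. For the difference between lines, 2068 genes were called, against 944 without the MOLT-4 replicate 2 libraries, 1307 with DESeq2, 1178 at an adjusted p below 0.01, and 1367 to 2196 without 1 library. Overlap of calls between cell lines went from 3557 to 2241 genes with DESeq2. With an estimated correlation, 0 of the lists passed camera in DND-41, 0 in MOLT-4 and 0 for the difference, against 6, 10 and 12 at the preset correlation. That form of camera had little power with so few libraries, so a failure to pass it does not by itself count against a list. In DND-41 the estimate was 0 for cytokine receptors and −0.085 for NOTCH targets, both below the preset 0.01. A larger correlation therefore did not end these calls. Other estimates lay far above the preset. They were 0.636 in MOLT-4 and 0.351 for the difference for cholesterol synthesis, and 0.906 and 0.895 for mitochondrially encoded genes. G2/M was at 0.239 for the difference. For such lists the p-values at the preset correlation may be too small. The causes of the other changes were not tested. Fry, which tests a list against no change where camera tests it against the other genes, gave 6, 10 and 13 lists, not the same ones. Those past camera and not past fry were interferon response in DND-41, T-ALL transcription factors and mitochondrially encoded genes in MOLT-4, and these 2 lists and G2/M for the difference. Those past fry alone were ribosome biogenesis in DND-41 (adjusted p = 0.0473), apoptosis regulators and p53 targets in MOLT-4 (0.00425 and 0.0223), and cytokine receptors, ribosome biogenesis, p53 targets and polycomb for the difference (0.0268, 0.0411, 0.0188 and 0.0281).

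Of the values of genes in the line or comparison for which the rule named them and of lists that passed camera, 2808 kept direction and side of the threshold, 135 kept direction and no longer passed, 4 newly passed and 10 changed sign. PBRM1 in DND-41 ranged from −0.034 to 0.148 and RUNX1 in MOLT-4 from −0.149 to 0.002 without 1 library. COL1A1 in MOLT-4 ranged from −12.14 to 1.351 without 1 library and was at −8.505 without both replicate 2 libraries. For the difference between lines, the median of T-ALL transcription factors ranged from −0.050 to 0.102 without 1 library (−0.020 and −0.004 among the values), and was −0.116 with library size alone and −0.022 without mitochondrially encoded genes, against 0.006. The G1/S median was −0.039 with library size alone, against 0.084. Genes that the text names were also traced outside the comparison that named them. Without 1 library, MT-ND6 in DND-41 went from 0.072 to −0.242 and 0.326, RAG1 in MOLT-4 from 0.028 to −0.174 and 0.282, and both passed at each end. Of the genes that the text names, leaving out 1 library ended a call for 10 of 112 tested in DND-41, 8 of 116 in MOLT-4 and 19 of 120 for the difference, and 7, 2 and 9 newly passed. The cause of these changes was not tested.

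With the replicate block, 6876 genes were called in DND-41, 6920 in MOLT-4 and 2579 for the difference. MYB in DND-41 then passed (−0.15, adjusted p = 0.0210), and the list of T-ALL transcription factors no longer passed for the difference (0.006, adjusted p = 0.156). The pairing of the libraries is not given in the sources used here. The main fit had no block because the labels do not pair the libraries. Same-numbered libraries deviated together with Pearson's r = 0.084 in DND-41 and 0.275 in MOLT-4 over 2 pairs each, too few to show whether they were paired. Both MOLT-4 replicate 2 libraries shared the stromal signal described above. Depth leaves levels below about 0.15 CPM unresolved.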

Other observations

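The tests of genes restricted to 1 line were chosen before their results were seen, and the genes of this paragraph after their values were seen. LCP2, an adaptor of the T-cell receptor, fell in DND-41 (−0.73 ± 0.06) and MOLT-4 (−2.02 ± 0.08), as did the zeta chain gene CD247 (−0.44 ± 0.06 and −1.35 ± 0.06). CD7, a surface marker of early T cells, fell from 2199 ± 19.98 to 1115 ± 40.3 CPM in DND-41 and from 70.1 ± 0.571 to 26.8 ± 2.56 CPM in MOLT-4. RAG1, which cuts DNA in antigen receptor joining, rose in DND-41 (0.53 ± 0.06), where its partner RAG2 fell (−0.45 ± 0.06).

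Genes expressed mainly in 1 line were hypothesised to fall more after ACBI-1 than genes at similar levels expressed in both. They were picked in DMSO replicate 1 of each line and their effect was taken from the other libraries. For 322 DND-41-restricted genes the median log2 fold change in DND-41 was −0.576, where 10000 random lists matched for level gave −0.011 to 0.071 (middle 95%). For 444 MOLT-4-restricted genes the median in MOLT-4 was −0.333, against 0.007 to 0.073. The random lists take genes as independent, which they are not, and do not measure the spread between libraries. Each effect compared both ACBI-1 libraries with DMSO replicate 2 alone. Within these limits, both values went with the hypothesis. It could reflect a larger need for BAF activity at line-restricted genes, a reading not tested here.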
